A study of Mus musculus with 24 samples.

How the data were processed

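Gene expression was measured in heart RNA of 24 male mice aged 8 weeks with single-colour Agilent 8x60K arrays, 1 array per animal. The 4 groups were uninfected BALB/c, infected BALB/c, uninfected C57BL/6J and infected C57BL/6J mice, with 6 arrays each. The infected animals had received tissue-derived trypomastigotes, the form in which the parasite travels in blood, of the Tulahuen strain of Trypanosoma cruzi. In each strain, replicates 1 to 3 of the infected animals carried a labelled parasite dose of 200 and replicates 4 to 6 a labelled dose of 150. The unit of the dose is not given in the sources used here.

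The deposited scanner files give, per the file headers, the signal intensity of each spot as background-subtracted and detrended by Feature Extraction 11.5.1.1, with marks for spots well above background and for outlying spots. The deposited value table holds log2 values. Per the labels, the authors used Partek, whose version is not given in the sources used here. The table was checked against the scanner files. After quantile normalisation of the log2 processed signal, 99.8% of its values lay within 0.1 of the value at the same rank, and every column had a median of 3.39.

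The text starts from the scanner files. Each array held 62976 spots, of which 59305 were not control spots and stood for 55681 probes. Spots marked as outliers were set to missing, repeated spots were averaged, and each array's log2 signal was scaled by subtracting its 75th percentile. A gene can thus have fewer values than its group has arrays. Probes were matched to gene symbols through the RefSeq identifiers on the array and a mouse RefSeq table. This named 27509 probes and 20887 genes and left 28172 probes without a name, of which 16194 carry only a chromosomal region. Probes well above background on at least 6 of the 24 arrays were kept, and the probe with the highest mean stood for each gene, which left 18002 genes. In place of read depth, the share of probes well above background is given for each array. It ranged from 28.3% to 92.8%, and the number of arrays limits the precision. A high share is no sign of a better array. On the array with the highest share, C57BL/6J control replicate 5, 56.53% of spots were marked as outlying. Its median rank correlation with the other arrays was 0.37.

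Group means were compared with limma 3.58.1 in R 4.3.3, with 1 mean per strain and infection group and 20 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All p-values of limma are two-sided. The comparisons were infection within each strain, the difference of the responses between strains (the interaction), the strains within control and within infected animals, and dose. Infection at the labelled dose of 200 against all controls of a strain was fixed as an alternative, and was made a comparison of its own after the data were seen. The infected arrays of the labelled dose of 150 were left out of that fit. Data handling used the R packages data.table (1.17.8) and jsonlite (2.0.0), and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

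Fixed gene lists, 45 in number, covered AKT signalling, contraction and the other functions of heart muscle, metabolism, the interferon and immune systems, and markers of cell types that heart tissue or a careless dissection might hold. They were written from general knowledge and share some genes. Each list was tested against all other genes with camera of limma at a preset correlation of 0.01 and, as an alternative, with the correlation estimated from the residuals. A list's score on an array is the median over its genes of the log2 value minus the mean of the same strain's controls. The samples, groups, comparisons, gene lists, tests, rule for named genes and first set of alternatives were fixed before the data were examined.

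The rule named, per comparison, up to 10 genes with the highest and 10 with the lowest log2 difference among genes with an adjusted p under 0.05, a log2 difference of at least 1, no overlap between the groups' arrays and a symbol that is not a clone or accession name. It also took up to 4 members of each described list with the lowest adjusted p, and any member of the AKT and contractility lists. Where a gene was not well above background on any array of a group, its fold is given as a lower bound, taken from the lowest signal that was still well above background on those arrays. Such a bound is for the 1 probe that stands for the gene and carries no standard error. Of 220 combinations of a named gene and a comparison, 51 had several probes, none of which was called in the opposite direction, and in 4 a probe had the opposite sign without a call. Results of 3 genes that were named or flagged are not reported here.

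The alternatives were normexp background correction with an offset of 50, quantile normalisation, scaling by the median, the deposited value table, no filter or a filter of all arrays on dim probes, the mean over a gene's probes, slide as a block, a variance trend with a robust fit, no moderation of the variance, an estimated list correlation, only the arrays compared, infected animals of 1 dose, dose within each strain, and leaving out each array in turn. The scanner files lack the mean spot signal, so normexp used the median spot signal. A block for the scan date was not run, since all arrays were scanned on 1 day. Fits to each slide, fits without the 4 arrays of high signal and fits without infected replicate 5 of each strain were added after the data were seen.

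The model was also tested on simulated data with known changes of 50 genes per size. In the comparison of infected with uninfected BALB/c, 36% of genes changed by 2 on the log2 scale and 84% of genes changed by 4 were recovered. At the labelled dose of 200 in C57BL/6J these shares were 8% and 58%. Of 10 lists raised by 1, all 10 were called, and none of the others, with genes simulated as independent of each other. On the real arrays, however, other divisions of the same arrays called a median of 7 to 21 lists at the preset correlation, depending on the comparison. Permutation tests of correlations over arrays and Fisher's exact test of counts were two-sided and were run in R. Probes without a gene name were left out of the gene comparisons and tested apart. Animals beyond the 6 per group on the arrays were not analysed here.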

Results

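The series concerns genes of the AKT network and the weakened contraction of the mouse heart in acute infection with Trypanosoma cruzi, the protozoan that causes Chagas disease. Heart RNA of 24 male mice was hybridised to 1 array each. Uninfected and infected BALB/c and C57BL/6J mice made up 4 groups of 6 arrays. The arrays lay on 3 slides of 8, and each slide held 2 arrays of every group and 1 infected array of each strain and dose. On every slide controls lay in columns 1 and 2 and infected arrays in columns 3 and 4, with dose 150 in 3 and dose 200 in 4, and BALB/c lay in row 1 and C57BL/6J in row 2. Position therefore cannot be told apart from infection, strain or dose. Values are log2 signals relative to the 75th percentile of the array. Differences of single genes between groups are followed by their standard error, except where an array or a setting was changed, and folds are the same differences on the linear scale.

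The arrays measured very different amounts of signal. The median array had 48% of its probes well above background, and its 75th percentile of processed signal was 38.8. Across arrays the 75th percentile ran from 8.2 to 1592.3. On 4 arrays, 1 in each group, its log2 was above 8. These were BALB/c control replicate 2 at 8.81, BALB/c infected replicate 4 at 8.91, C57BL/6J control replicate 5 at 10.64 and C57BL/6J infected replicate 6 at 9.98. Between 81.2% and 92.8% of their probes were well above background. Rank correlations between arrays ran from 0.13 to 0.95, with a median of 0.74.

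**Figure D1:**
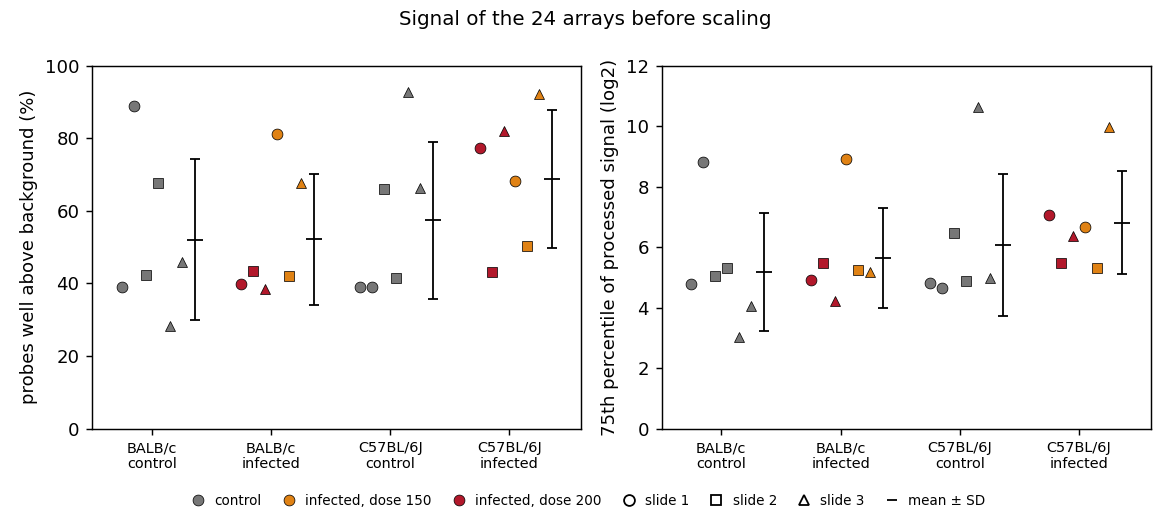
Share of probes well above background (%, left) and 75th percentile of the processed signal (log2, right) of the 24 arrays by group, coloured by labelled dose and shaped by slide, with the mean and SD of each group. In every group 1 array had a 75th percentile above 8 on the log2 scale, the highest at 10.64.

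In infected BALB/c hearts, genes of the interferon response, antigen presentation and T cells stood above the uninfected hearts. The interferon-inducible GTPases, which attack the compartments in which intracellular parasites live, had a median log2 difference of 4.23 over 17 measured genes. T cell markers had a median of 3.54 over 25 genes. Over all genes, 5 genes rose and none fell. They were Cxcl9, a chemokine that draws activated T cells (at least 70.4-fold), Zbp1, a sensor of nucleic acids that triggers cell death (7.04 ± 1.23, a further probe 3.2), Apol9b, an interferon-induced apolipoprotein L (5.50 ± 0.93), Upb1, an enzyme of pyrimidine breakdown (2.58 ± 0.45), and Gm4951. Each had an adjusted p of 0.0384. A further probe of Cxcl9 had a difference of 5.31 on the log2 scale. Apol9b had values on 5 of 6 control arrays. Cxcl9 and Zbp1 were well above background on 5 of 6 infected arrays, and Zbp1 on 1, Apol9b on 4 and Upb1 on 2 of 6 control arrays. Gm4951, at 5.053 ± 0.906, was named after its value was seen.

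Lists gave a broader picture than single genes. Of 45 lists, 20 were shifted up and 9 down, and 17 of these held with an estimated correlation. No GTPase passed over all genes, and all 17 rose adjusted over the list alone (adjusted p = 0.014 with an estimated correlation). For T cell markers these counts were 0 and 20 (0.014 likewise), for the type I interferon response 1 and 17 (0.014), and for MHC class I presentation 0 and 14 (0.019). Chemokines counted 1 over all genes and 11 adjusted over the list alone (0.014). Macrophage and monocyte markers had a median of 2.33, with 0 and 19 genes (0.017). The call of 5 genes was lost without any 1 of 16 arrays, among them all 6 BALB/c controls, and with slide as a block, which gave 0 genes. It became 442 genes without BALB/c infected replicate 5, 146 without C57BL/6J infected replicate 5, 73 without BALB/c infected replicate 4, 63 without C57BL/6J infected replicate 6, 56 without C57BL/6J infected replicate 2, 30 without C57BL/6J control replicate 5 and 9 without C57BL/6J infected replicate 4.

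The GTPase score of BALB/c infected replicate 5 was 0.57 and that of C57BL/6J infected replicate 5 was 0.03. The other 10 infected arrays lay between 1.39 and 5.95 and the controls between -2.66 and 0.84. Both of these arrays carried the labelled dose of 150 and lay in column 3 of slide 2. All 6 infected arrays of the labelled dose of 200 had a score of at least 3.66.

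**Figure D2:**
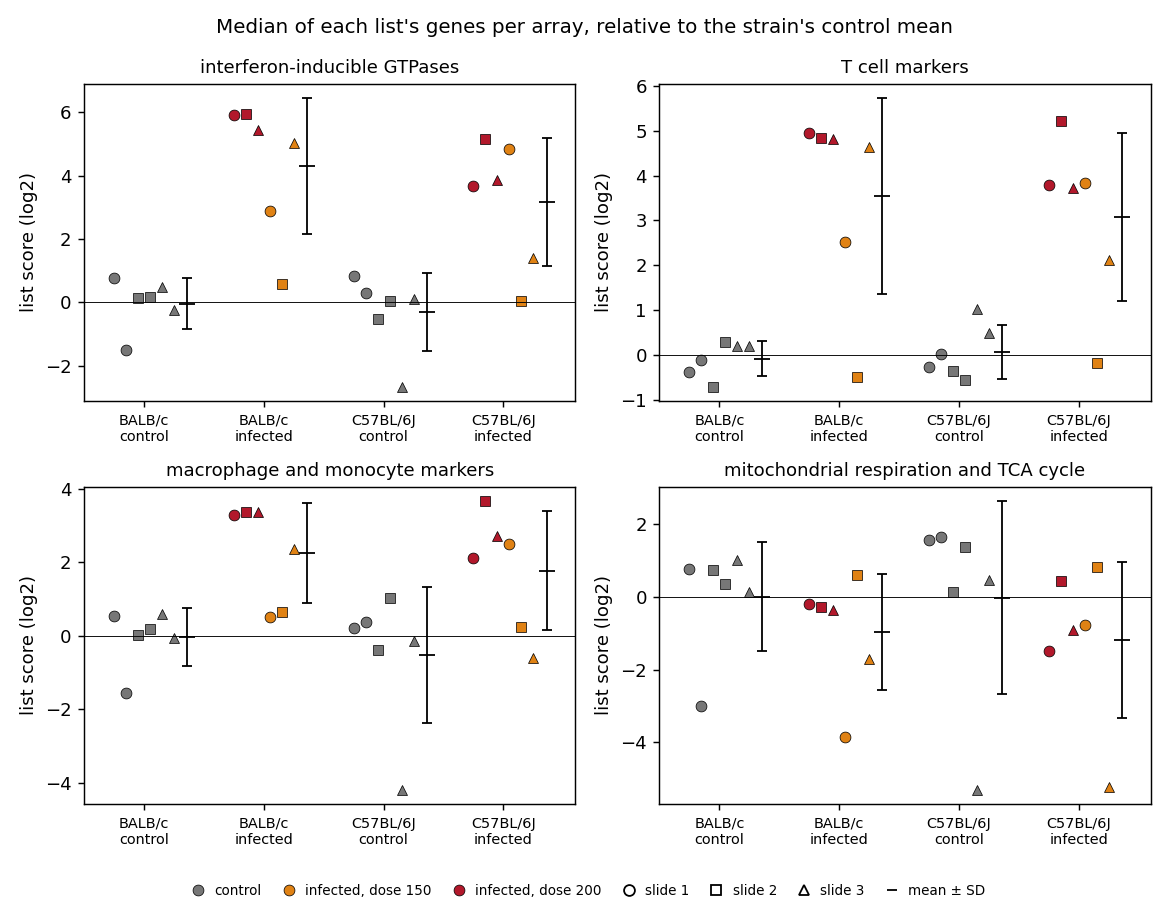
Scores of gene lists per array (median log2 of the list's genes relative to the strain's control mean) by group, coloured by labelled dose and shaped by slide, with group mean and SD. Infected replicate 5 of each strain had a GTPase score of 0.57 or 0.03, and the other 10 infected arrays had scores of 1.39 to 5.95.

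At the labelled dose of 200, infected BALB/c hearts (3 arrays against 6 controls) had 616 genes that rose and 60 that fell. Cxcl9 rose at least 302-fold (adjusted p 3.51e-06), Ccl5, which attracts T cells and monocytes, by 8.91 ± 0.82 (481-fold, adjusted p 2.75e-06), and Ccl8 by 8.44 ± 0.61. The bound for Cxcl9 holds for 1 probe, and a further probe rose by 7.39 on the log2 scale. Zbp1 rose by 9.03 ± 0.59 (a further probe 4.49), with 1 control array well above background. Cxcl10, a further T cell chemokine, was at least 71-fold higher. Ccl8 was well above background on 5 of the 6 control arrays and Ccl5 on all. Saa3, an acute-phase protein, rose by 7.92 ± 0.67, Ubd, a ubiquitin-like modifier, by 7.63 ± 0.68 and Cfb, complement factor B, by 7.55 ± 0.95, with 3, 2 and 2 control arrays well above background.

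Genes that defend cells against intracellular microbes rose as a group. All 17 measured interferon-inducible GTPases rose, with a median of 5.75 (adjusted p = 0.00054 with an estimated correlation). Igtp rose by 8.44 ± 0.76, Irgm1 by 5.75 ± 0.44 and Gbp6 by 5.45 ± 0.46, with values on 6, 5 and 6 control arrays. In the type I interferon response 13 of 25 genes rose over all genes and 25 adjusted over the list alone (0.005), among them Isg15, a ubiquitin-like protein, by 4.24 ± 0.52. In the interferon-gamma axis these counts were 12 and 14 of 22 (0.00078), with Socs1, a brake on cytokine signalling, at 4.75 ± 0.49 and 4 control arrays well above background. Innate sensing and NF-kappaB counted 11 and 19 of 31 (0.017), with Casp1, the inflammasome protease, at 3.54 ± 0.47.

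Antigen presentation rose in both branches. MHC class I presentation counted 14 and 18 of 21 genes (adjusted p = 0.015 with an estimated correlation), with Psmb8, a subunit of the immunoproteasome, at 6.06 ± 0.65, and Nlrc5, the activator of class I genes, at 5.86 ± 0.49 with 3 control arrays well above background. MHC class II presentation counted 9 and 12 of 15 (0.0013). H2-Ab1 rose by 6.34 ± 0.72, H2-DMb1 by 6.95 ± 0.96 and Cd74, the invariant chain, by 5.68 ± 0.66.

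Markers of immune cells rose with them. T cell markers counted 18 over all genes and 21 adjusted over the list alone of 25 (adjusted p = 0.00054 with an estimated correlation). Lck, the kinase of the T cell receptor, rose by 7.48 ± 0.53 and Cd3d, a receptor chain, by 6.56 ± 0.51, with 2 and 1 control arrays well above background. Cytotoxic effector genes counted 10 and 13 of 19 (0.00054), including Nkg7, a granule protein, at 5.19 ± 0.52. Macrophage and monocyte markers counted 18 and 20 of 28 (0.0056), and 1 gene fell adjusted over the list alone. Mpeg1, a pore-forming protein of macrophages, rose by 5.09 ± 0.40. Dendritic cell markers counted 6 and 8 of 13 (0.015), chemokines 13 and 17 of 25 (0.0013) with 1 that fell adjusted over the list alone, leukocyte adhesion 6 and 9 of 16 (0.001), and complement 10 and 12 of 18 (0.015). Immune checkpoint and regulatory genes counted 4 and 4 of 14 (0.015), led by Cd274, the ligand that restrains T cells, at least 83.1-fold higher. Cytokines and the TNF family counted 6 and 7 of 27 (0.035). Cell cycle genes counted 14 and 18 of 27 (0.0074), with Mki67, a marker of dividing cells, at 3.33 ± 0.37.

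Other lists moved less or lost their call. Apoptosis and cell death counted 4 and 8 of 23 (adjusted p = 0.12 with an estimated correlation), arginine, alternative activation and type 2 genes 4 and 4 of 18, with 1 that fell adjusted over the list alone (0.12), and neutrophil markers 3 and 7 of 16 (0.05). Matrix proteases and inhibitors counted 2 and 2 of 24 (0.45), glycolysis 1 and 4 of 22 (0.79), and fibroblast markers and ribosomal proteins 0 of 16 and 0 of 24 (0.74 each). Ass1, which makes the precursor of arginine, rose by 3.31 ± 0.55. Mast cell and eosinophil markers were the 1 list shifted down, with a median of -1.06 and 2 of 15 genes that fell (0.2). These were the mast cell proteases Mcpt4, at least 6.33-fold lower, and Cpa3, at least 1.51-fold lower. They were well above background on 6 and 3 of the 6 control arrays. Among B cell and plasma cell markers 2 of 14 rose, Jchain, the joining chain of secreted antibodies, at least 8.30-fold and Blnk by 1.39 ± 0.34, and the list had a median of -0.31, a mean of 0.23 and a test direction up. Dbh, which makes noradrenaline, was well above background on every array and fell by 2.78 on the log2 scale ± 0.50 (adjusted p 0.00244). Mcpt4 lost its call without infected replicate 1 (-2.91) or 2 (-3.13), and Blnk without BALB/c control replicate 1 (1.31), 3 (1.34) or 4 (1.37) or infected replicate 1 (1.5), 2 (1.43) or 3 (1.25).

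With slide as a block 650 genes changed in BALB/c at the labelled dose of 200, and the slides alone gave 0, 3 and 18 genes. The GTPase medians within slides were 5.93, 5.86 and 5.50, and those of T cell markers 5.03, 4.89 and 4.27, against 5.76 and 4.95 with the block. Without infected replicate 2 the count was 405 and without infected replicate 1 it was 423. Over the genes well above background on all arrays, the median was 6.09 for GTPases and 2.89 for T cell markers.

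**Figure D3:**
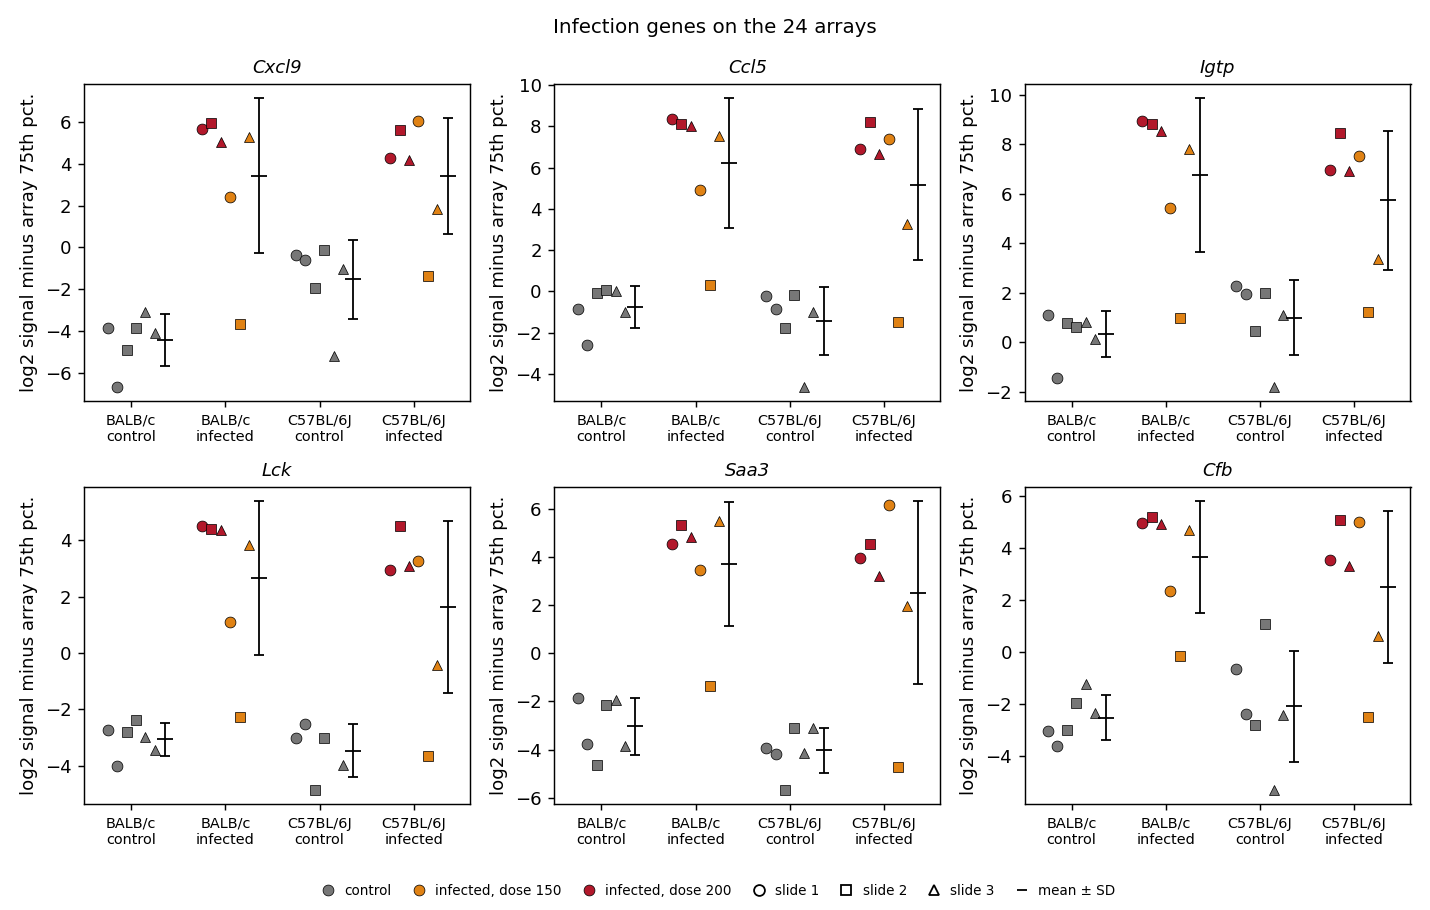
Log2 signal relative to the array's 75th percentile of genes raised in infection, per array and group, coloured by labelled dose and shaped by slide, with group mean and SD. Igtp averaged 8.77 in BALB/c and 7.45 in C57BL/6J infected at the labelled dose of 200, against 0.33 and 0.99 in the controls.

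In infected C57BL/6J hearts of both doses, T cell and defence genes again stood highest. GTPases had a median of 2.92, T cell markers of 3.30 and cytotoxic effector genes of 2. Adjusted over the list alone, 17 of 17 GTPases, 16 of 25 T cell markers and 10 of 19 cytotoxic genes rose. No gene passed over all genes with limma. At an unadjusted p under 0.05 the count was 1702 (9.5%), and an unmoderated linear model also gave 0. Ccl5 had a difference of 6.60 ± 1.41 and Zbp1 of 4.98 ± 1.23, each with an adjusted p of 0.279, and were well above background on 5 and 2 of the 6 control arrays. Of 45 lists 19 were shifted up and 9 down, and none held with an estimated correlation (lowest adjusted p = 0.11). The count became 148 without C57BL/6J infected replicate 5 and 21 without BALB/c infected replicate 5, and it stayed 0 with slide as a block.

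Infected C57BL/6J hearts at the labelled dose of 200 had 370 genes that rose and 20 that fell. Of the 84 divisions of these arrays into groups of the same sizes, the real one included, 5 called as many genes. Ccl5 rose by 8.70 ± 0.82 (415-fold, adjusted p 8.92e-06), Saa3 by 7.91 ± 0.67 and Ubd by 7.38 ± 0.71. Ms4a4b, a membrane protein of T cells, was at least 45.2-fold higher. Ccl5 was well above background on 5, Saa3 on 1 and Ubd on 2 of the 6 control arrays. Ifng, the main activator of macrophages, rose by 5.89 ± 0.66, with 1 control array well above background.

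The same defence lists rose in this strain. Of 45 lists 20 were shifted up and 8 down, and 16 held with an estimated correlation, all of them up. GTPases counted 16 genes over all genes and 17 adjusted over the list alone of 17, with a median of 4.32 (adjusted p = 0.00083 with an estimated correlation). Igtp rose by 6.45 ± 0.76 and Irgm1 by 4.43 ± 0.44. T cell markers counted 14 and 21 of 25 (0.00024), with Lck at 6.98 ± 0.55 and Cd3d at 6.51 ± 0.51 and 1 and 2 control arrays well above background. Cytotoxic effector genes counted 10 and 11 of 19 (0.00017), with Nkg7 at 4.05 ± 0.52. MHC class II presentation counted 9 and 13 of 15 (0.00086), and Ctss, the protease that trims the invariant chain, rose by 5.08 ± 0.90. MHC class I presentation counted 6 and 14 of 21 (0.029), the interferon-gamma axis 9 and 14 of 22 (0.00086) and the type I interferon response 5 and 12 of 25 (0.029). Macrophage and monocyte markers counted 14 and 21 of 28 (0.0043), with Mpeg1 at 4.38 ± 0.40. Chemokines counted 6 and 16 of 25 (0.0016), and 1 member of each of these last lists fell adjusted over the list alone. Complement counted 2 and 12 of 18 (0.029), innate sensing and NF-kappaB 10 and 11 of 31 (0.029), leukocyte adhesion 5 and 9 of 16 (0.00086) and dendritic cell markers 2 and 7 of 13 (0.029). Immune checkpoint and regulatory genes counted 4 and 6 of 14 (0.0023), cytokines and the TNF family 3 and 4 of 27 (0.0048), and cell cycle genes 5 and 18 of 27 with 1 that fell adjusted over the list alone (0.0096). Mki67 rose by 2.16 ± 0.37 (a further probe 0.87).

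Genes that fell in C57BL/6J at this dose included Retnla, a marker of alternatively activated macrophages, at least 18.7-fold lower, and Penk, the precursor of enkephalins, by 4.33 on the log2 scale ± 0.84, with 2 of 3 infected arrays well above background. Penk lost its call without infected replicate 1 (-3.23). Retnla, with a fitted difference of -4.6, lost its call with normexp (-1.05), quantile normalisation (-3.82), the deposited value table (-3.82) or only the arrays compared (-4.6, so that the error term and not the difference ended it). Neutrophil markers counted 1 of 16 over all genes (adjusted p = 0.24 with an estimated correlation), apoptosis and cell death 2 of 23 (0.19), arginine, alternative activation and type 2 genes 2 that rose and 1 that fell of 18 (0.11), and matrix proteases and inhibitors 1 of 24 (0.59). Endothelial markers had a median of -0.62 (0.63), smooth muscle and pericyte markers of -0.63 (0.59) and the dystrophin complex and costamere of -0.47 (0.59), with no gene that passed. With the deposited value table these 3 medians were 0, 0.12 and 0.

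With slide as a block 347 genes changed in C57BL/6J at the labelled dose of 200, and the slides alone gave 0, 1 and 6. The GTPase medians within slides were 3.16, 5.42 and 4.15 and those of T cell markers 3.76, 5.04 and 2.56, against 4.31 and 4.17 with the block. The count was 182 without C57BL/6J infected replicate 2, 606 without BALB/c control replicate 2 and 141 in a fit of only the arrays compared.

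**Figure D4:**
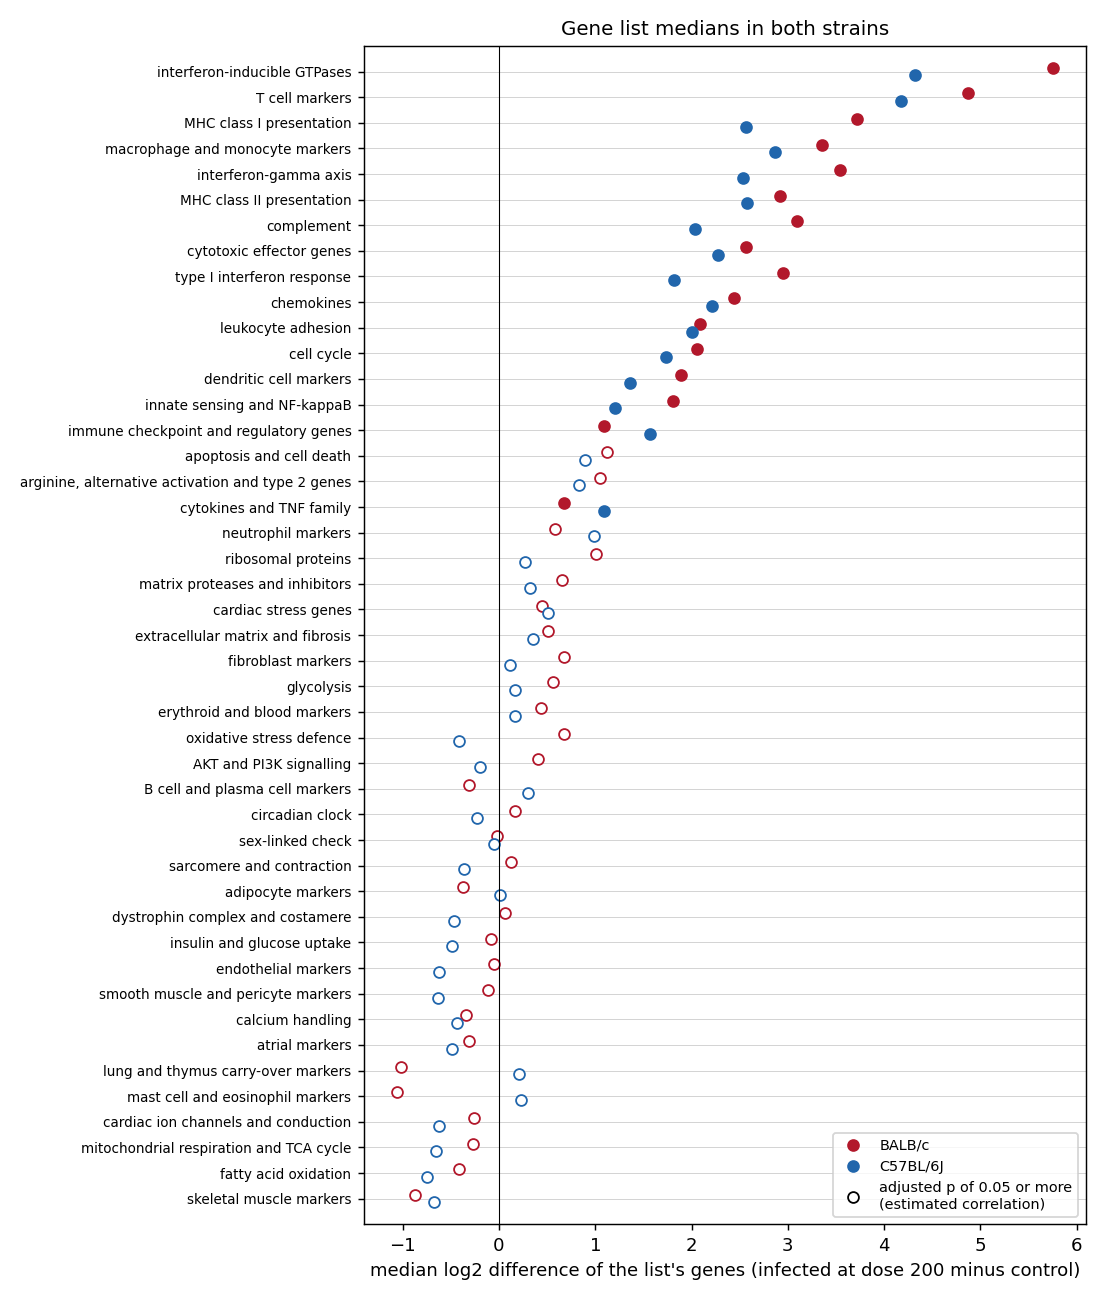
Median log2 difference of each list's genes between infected hearts at the labelled dose of 200 and controls, for BALB/c and C57BL/6J, with open points for an adjusted p of 0.05 or more with an estimated correlation. GTPases had the highest medians, 5.75 and 4.32, and lists near 0, such as the sarcomere list at 0.12 and -0.36, changed sign under other scalings.

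The AKT and PI3K signalling list, which carries growth and survival signals downstream of insulin, had no call for infection in either strain, over both doses or at the labelled dose of 200. In BALB/c at the labelled dose of 200, 1 of its 50 measured genes rose. This was Trib3, a pseudokinase that binds AKT, by 2.60 ± 0.50 (adjusted p 0.00479). Akt1 and Akt2, which encode forms of the kinase itself, had differences of 0.53 ± 1.18 and 0.39 ± 1.15 in BALB/c, and of 0.09 ± 1.18 and 0.09 ± 1.15 in C57BL/6J. Pik3r5 and Pik3cg, subunits of the PI3-kinase of white blood cells, had differences of 2.99 ± 0.80 (adjusted p 0.0533) and 2.06 ± 0.69 (0.154) in BALB/c. In C57BL/6J none of the 50 genes passed, and Pik3cg stood highest at 2.35 ± 0.71 (adjusted p 0.135).

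The median of the AKT list was 0.40 in BALB/c (adjusted p 0.0866, and 0.85 with an estimated correlation) and -0.20 in C57BL/6J (adjusted p 0.495, and 0.91). Within slides it was 1.24, -0.04 and -0.10 in BALB/c and -1.76, 0.39 and 0.33 in C57BL/6J, against 0.40 and -0.19 with the block. In C57BL/6J it was 0.01 with normexp and 0.15 with the deposited value table. Over all infected animals the median was -0.19 in BALB/c, where the mean was -0.02 and the test direction up (adjusted p 0.9), with 1 gene that rose adjusted over the list alone. In C57BL/6J it was -0.52 (adjusted p 0.212).

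Genes of contraction and of the energy supply of the heart stood lower in infected animals of both doses, without a gene that passed. The sarcomere and contraction list had a median of -0.56 in BALB/c (adjusted p = 0.66 with an estimated correlation) and -0.83 in C57BL/6J (0.59). Calcium handling, which couples excitation to contraction, had medians of -0.58 (0.6) and -0.83 (0.56), and cardiac ion channels and conduction -0.55 (0.43) and -0.90 (0.46). Mitochondrial respiration and the TCA cycle had -0.97 (0.63) and -1.13 (0.58), fatty acid oxidation -1.06 (0.6) and -1.16 (0.56), and insulin and glucose uptake -0.58 (0.65) and -0.96 (0.59). Over the 12 control arrays, which hold no infection, the score of the mitochondrial and fatty acid genes fell with the share of probes well above background (Spearman's rho -0.88, permutation p = 0.00034). Atp2a2, the calcium pump of the sarcoplasmic reticulum, had differences of -1.06 ± 0.90 and -2.07 ± 0.94, Ryr2, its release channel, of -0.89 ± 0.67 and -1.35 ± 0.74, and Myh6, the main heavy chain of cardiac myosin, of -0.53 ± 1 and -0.89 ± 1, with adjusted p of 0.514 or more. All genes together had medians of -0.148 and -0.163 in these comparisons, and of 0.141, 0.167, 0.321, 0.32 and 0.24 for the interaction, the strains in controls, the strains in infected animals, dose and the interaction at the labelled dose of 200.

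At the labelled dose of 200 the sarcomere, calcium handling, ion channel, fatty acid oxidation and mitochondrial lists had a call down in C57BL/6J and none in BALB/c, and no call held with an estimated correlation. C57BL/6J infected replicates 1 and 3 had 77.2% and 81.9% of probes well above background, against 43.2% on replicate 2 and 38.4% to 43.4% on the BALB/c arrays of this dose. Sarcomere and contraction had a median of 0.12 in BALB/c, where its mean was 0.07 and its test direction down (adjusted p = 0.98 with an estimated correlation), and of -0.36 in C57BL/6J (0.71). Calcium handling had medians of -0.34 (0.97) and -0.44 (0.63), ion channels of -0.26 (0.74) and -0.62 (0.54), fatty acid oxidation of -0.42 (0.97) and -0.75 (0.71), and mitochondrial respiration of -0.27 (0.97) and -0.65 (0.71). Within slides the C57BL/6J medians of the sarcomere list were -2.44, 0.12 and 1.04, those of fatty acid oxidation -2.79, -0.34 and 1.26 and those of mitochondrial respiration -2.92, -0.29 and 1.51. With quantile normalisation the sarcomere and calcium medians of C57BL/6J turned to 0.07 and 0.02, and the sarcomere median of BALB/c to -0.21. From the deposited values these medians were 0.14, 0 and -0.21, and with median scaling the last was -0.08. Cardiac stress genes, such as natriuretic peptides, had medians of 0.45 and 0.51, and 1 of 22 rose in BALB/c, the protease inhibitor Timp1 by 4.29 ± 1.06. Timp1 lost its call without BALB/c infected replicate 1 (4.73), 2 (4.32) or 3 (3.84) or control replicate 3 (4.26), 4 (4.23) or 6 (4.17).

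The remaining lists had no call at the labelled dose of 200. Their medians in BALB/c and C57BL/6J were 0.51 and 0.35 for the extracellular matrix and fibrosis, -0.31 and -0.49 for atrial markers (1 of 12 rose in BALB/c), -0.87 and -0.67 for skeletal muscle markers, -0.37 and 0.01 for adipocyte markers, 0.44 and 0.17 for erythroid and blood markers, and 0.67 and -0.42 for oxidative stress defence. The circadian clock had 0.17 and -0.23, lung and thymus carry-over markers -1.02 and 0.21, and the Y-linked genes of the sex check -0.02 and -0.05. In BALB/c the endothelial, smooth muscle and dystrophin lists had -0.05 (1 of 22 rose), -0.11 and 0.06, the last with its test direction down, and insulin and glucose uptake had -0.08 and -0.49. In C57BL/6J glycolysis had 0.17 (1 of 22 rose), fibroblast markers 0.11 with a mean of -0.03, mast cell markers 0.23 with its test direction down, B cell markers 0.30 (1 of 14 rose), and ribosomal proteins 0.27 with a mean of 0.14 and a test direction down.

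Some of these medians changed sign under another scaling. In BALB/c quantile normalisation gave 0.25 for B cell markers, -0.11 for the dystrophin complex and 0.15 for the Y-linked genes, normexp 0.02 for endothelial markers and median scaling -0.03 for the circadian clock. In C57BL/6J median scaling gave -0.08 for glycolysis, -0.20 for fibroblast markers, -0.11 for mast cell markers, -0.33 for adipocyte markers and -0.07 for ribosomal proteins. Normexp gave -0.17 for B cell markers, -0.14 for lung and thymus carry-over markers and 0.09 for the Y-linked genes, and quantile normalisation 0.26 for oxidative stress defence.

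The genes that rose in the strains overlapped. At the labelled dose of 200, 338 genes rose in both, where 12.7 would be shared if the calls were independent, and no gene was called in opposite directions. Of the 60 genes that fell in BALB/c and the 20 in C57BL/6J, 1 was shared, against 0.1. The calls of both strains rest on 1 estimate of spread per gene and are not fully independent. Of all genes, 46.2% had the same sign in both strains at that dose. Across all 18002 genes the responses over both doses had a Pearson correlation of 0.511 and a Spearman correlation of 0.386, and at the labelled dose of 200 of 0.327 and 0.002. Genes are not independent replicates, and the jackknife standard error of the first value over arrays was 0.637. Within slides it was 0.552, 0.608 and 0.533, and it was 0.165 without BALB/c infected replicate 4.

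The difference of the responses was tested as an interaction. The response of GTPases was higher in BALB/c by a median of 1.19, of type I interferon genes by 0.92 and of MHC class I genes by 0.91, and these were the 3 of 45 lists with a call. None held with an estimated correlation (lowest adjusted p = 0.96). No gene passed with limma over both doses, where 123 (0.7%) had an unadjusted p under 0.05, or at the labelled dose of 200, where 400 (2.2%) did, and the unmoderated model gave 0 in each. Both shares lie below the 0.05 that no difference at all would give on average. Genes are not independent and the interaction was not simulated, so low shares do not show that the strains respond alike. At that dose 6 lists had a call (lowest adjusted p = 0.88 with an estimated correlation). GTPases differed by 1.48, type I interferon genes by 1.33, MHC class I genes by 1.07, mast cell markers by -1.12, oxidative stress defence by 0.65 and ribosomal proteins by 0.64. The last 2 were -0.24 and -0.25 with quantile normalisation and -0.27 and -0.44 with the deposited value table, and the mast cell difference was 0 with normexp. The slides alone gave GTPase differences of 2.77, 0.48 and 1.04 at that dose and of 0.68, 0.33 and 1.98 over both doses, against 1.47 and 1.21 with the block. The C57BL/6J arrays of that dose with 77.2% and 81.9% of probes well above background had GTPase scores of 3.66 and 3.86, the third, with 43.2%, had 5.14, and the BALB/c arrays had 5.43 to 5.95. The 3 lists became 0 without BALB/c infected replicate 2 or C57BL/6J infected replicate 5, 1 without BALB/c infected replicate 1, 3 or 6, 6 without BALB/c infected replicate 4, 12 without C57BL/6J control replicate 5 and 13 without BALB/c infected replicate 5. The 6 lists became 3 without C57BL/6J infected replicate 3, 10 without infected replicate 1 of either strain, 16 without C57BL/6J control replicate 5 and 18 without C57BL/6J infected replicate 2.

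Uninfected hearts of the strains differed in 67 genes, 40 higher and 27 lower in BALB/c. Acta1, the skeletal isoform of actin that the adult mouse heart keeps low, was 27.6-fold higher in BALB/c, at 8.99 ± 1.25 (SD, n = 6) against 4.21 ± 2.18 (difference 4.78 ± 0.94, adjusted p 0.0192). The lower mean includes 0.21 on C57BL/6J control replicate 5, where 56.53% of spots were marked as outlying. The other C57BL/6J controls had 3.82 to 6.24. Aqp6, a water channel, was higher by 7.16 ± 0.91, with 3 C57BL/6J arrays well above background, and Ifi202b, an interferon-inducible DNA sensor, by 4.22 ± 0.72, with 2. Tent5b was higher by 4.03 ± 0.51, the growth factor Fgf6 by 3.22 ± 0.53, Casq1, the calcium store of skeletal muscle, by 2.82 ± 0.49 and Hbb-b2, an adult beta globin, by 5.08 ± 1.03.

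Genes lower in BALB/c included Tnni3k, a kinase of heart muscle that binds troponin I, 17.8-fold lower at 0.83 ± 0.85 against 4.99 ± 0.53 (difference -4.15 ± 0.72, adjusted p 0.00534). Vps16, a part of the machinery that fuses endosomes, had a difference of -5.67 ± 0.78, Itpa, which clears faulty nucleotides, of -4.61 ± 0.72 and Rab6b, a transport GTPase, of -4.10 ± 0.45, with 2, 3 and 2 BALB/c arrays well above background. Among the lists, cardiac stress genes (median 0.97, with 2 of 22 higher, Acta1 and Gdf15), the extracellular matrix (0.81), matrix proteases and inhibitors (0.52, with Plau higher) and fibroblast markers (0.76) were up, and the type I interferon response (-0.39) and MHC class II presentation (-0.18) down. None held with an estimated correlation (lowest adjusted p = 0.99). MHC class II presentation had a median of 0.04 with normexp. On slide 1 the first 4 lists had -0.36, -0.55, -0.20 and -1.01.

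Acta1 lost its call without BALB/c control replicate 1 (4.56), 3 (4.71) or 5 (4.58) or C57BL/6J control replicate 3 (4.73), and Hbb-b2 without BALB/c control replicate 1 (4.99), 3 (4.84), 4 (5.01), 5 (4.81) or 6 (5.08) or C57BL/6J control replicate 2 (5.05) or 6 (5.07). The count was 60 with slide as a block and 0 on each slide alone. It was 30, 31, 37 and 40 without BALB/c control replicate 3, 1, 5 and 4, 36, 37, 39 and 41 without C57BL/6J control replicate 2, 1, 3 and 4, and 106 without BALB/c control replicate 2.

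**Figure D5:**
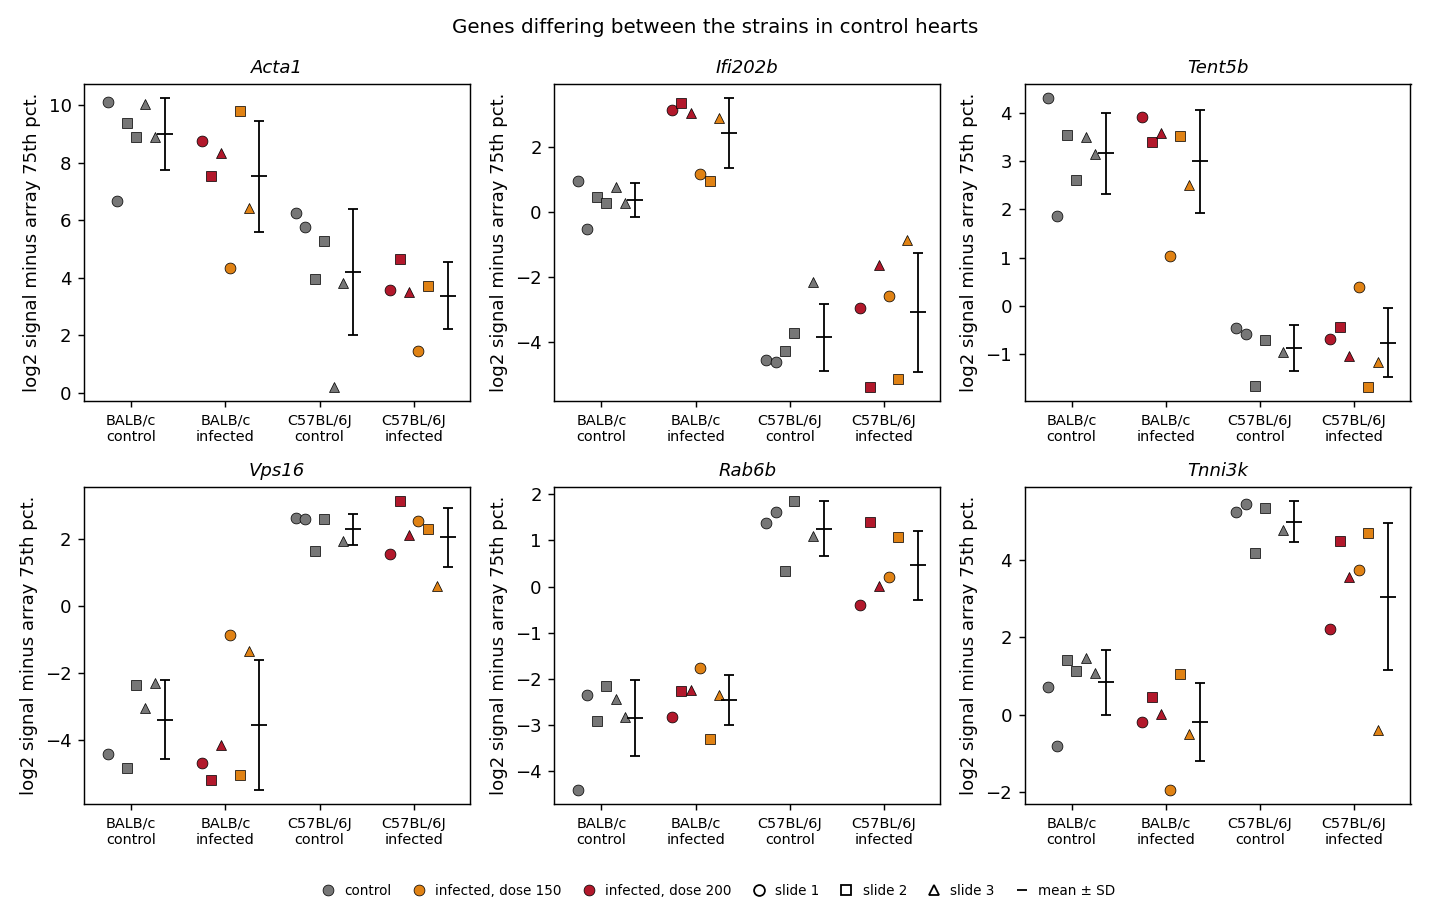
Log2 signal relative to the array's 75th percentile of genes that differed between the strains, per array and group, coloured by labelled dose and shaped by slide, with group mean and SD. Acta1 averaged 8.99 in BALB/c and 4.21 in C57BL/6J controls, and Tnni3k 0.83 and 4.99.

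Infected hearts of the strains differed in 71 genes, 48 higher and 23 lower in BALB/c. Of the genes called in controls, 22 of the higher and 19 of the lower were called here too, where 0.1 and 0 would be shared if the calls were independent. Ifi202b was higher by 5.51 ± 0.68, Serpina3f, a serpin induced in immune cells, by 4.62 ± 0.73 (a further probe -1.93), Tafa2, a secreted chemokine-like protein, by 5.01 ± 0.65 and Plau, the urokinase that activates plasmin, by 3.6 ± 0.48, with 4, 5, 1 and 1 C57BL/6J arrays well above background. Vps16 had a difference of -5.59 ± 0.71 with 2 BALB/c arrays well above background, and Il4ra, the receptor of interleukin 4, was at least 4.27-fold lower (adjusted p 0.00377), where a further probe had a difference of 0.67. Fibroblast markers (median 1.29), the extracellular matrix (0.98), MHC class I presentation (0.93), cardiac stress genes (0.90) and matrix proteases (0.82) were up, and none held with an estimated correlation (lowest adjusted p = 0.96).

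With slide as a block 74 genes and 3 lists differed, without MHC class I presentation and matrix proteases, and on each slide alone no gene did. The count was 26 without BALB/c infected replicate 1 or 3, 29 without 2 and 45 without 5, and 31, 33 and 38 without C57BL/6J infected replicate 1, 4 and 3. The lists became 2 without BALB/c infected replicate 1, 3 or 6 or C57BL/6J infected replicate 5, 3 without BALB/c infected replicate 2 or C57BL/6J infected replicate 6, 8 without C57BL/6J infected replicate 4, 14 without BALB/c infected replicate 4 and 17 without BALB/c infected replicate 5.

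Between the labelled doses of 200 and 150, infected hearts of both strains had higher medians of the defence lists at 200. GTPases differed by 2.60, T cell markers by 2.31, macrophage and monocyte markers by 2.18 and MHC class I presentation by 2.14, and 15, 15, 16 and 16 of their genes were higher adjusted over the list alone, with none over all genes. Glycolysis (1.39), ribosomal proteins (1.32), mitochondrial respiration (1.23), sarcomere and contraction (1.20) and AKT signalling (0.83) were also up, and mast cell markers (-1.07) and lung and thymus carry-over markers (-0.82) down. Of 45 lists 27 had a call, and none held with an estimated correlation (lowest adjusted p = 0.6). No gene passed with limma, where 1275 (7.1%) had an unadjusted p under 0.05, and the unmoderated model also gave 0. Without the 4 arrays of high signal, 2 of which carried the labelled dose of 150, the median over all genes went from 0.32 to 0.004, and the list medians were 0.21 for glycolysis, 0.20 for ribosomal proteins, -0.17 for mitochondrial respiration, -0.18 for fatty acid oxidation, 0.04 for sarcomere and contraction and 0.12 for AKT signalling, and with normexp those of mast cell and carry-over markers were 0.12 and 0.02. The GTPase difference was 0.76, 5.49 and 1.56 within slides, the second of which held infected replicate 5 of both strains, and 2.60 with the block, which gave 0 genes. Without these 2 arrays GTPases differed by 1.44, T cell markers by 1.27, macrophage and monocyte markers by 1.77 and MHC class I presentation by 1.94, and without them and the 4 arrays by 0.02, 0.32, 0.45 and 0.31.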

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

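The tests of a swap and of dose for infected replicate 5, and those of the strain genes higher in BALB/c, of the genes with no further probe and of high signal, were chosen after the data were seen. A sample is given here when its gap to the nearest other array of its group was large for the group's range by Dixon's test, which chance alone does in about 1 in 20 groups. It happened in 8 of 16 tests of array quality, 16 of 64 of list scores and 19 of 164 of gene levels, 16 of which are given below.

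The log2 75th percentile of signal was 8.91 on BALB/c infected replicate 4 (others of its group 4.21 to 5.46) and 10.64 on C57BL/6J control replicate 5 (4.65 to 6.46). Spots marked as outlying made up 19.89% on BALB/c control replicate 2 (others 0.28 to 0.45), 56.53% on C57BL/6J control replicate 5 (0.23 to 0.39) and 28.95% on C57BL/6J infected replicate 6 (0.29 to 0.9). The median rank correlation with the other arrays was 0.49 on BALB/c infected replicate 4 (0.72 to 0.84), 0.37 on C57BL/6J control replicate 5 (0.69 to 0.79) and 0.55 on C57BL/6J infected replicate 6 (0.73 to 0.79).

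On BALB/c control replicate 2 the scores were -2.06 for the type I interferon response (others -0.2 to 0.7), -2.57 for MHC class I presentation (-0.1 to 0.8), -1.56 for macrophage and monocyte markers (-0.05 to 0.6) and -1.93 for complement (0.08 to 0.6). C57BL/6J control replicate 5 had -3.2 for the type I interferon response (-0.55 to 0.65), -2.43 for the interferon-gamma axis (-0.32 to 0.44), -4.61 for MHC class I presentation (-0.11 to 1.32), -2.37 for MHC class II presentation (-0.51 to 0.46), -4.19 for macrophage and monocyte markers (-0.4 to 1.02), -1.88 for innate sensing and NF-kappaB (-0.39 to 0.46) and -3.71 for complement (-0.36 to 1.16). BALB/c control replicate 3 had -1.08 for cytokines and the TNF family (-0.2 to 0.3). BALB/c infected replicate 5 had -1.1 for cytotoxic effector genes (2.08 to 2.81), -0.14 for chemokines (2.17 to 2.54) and -0.39 for leukocyte adhesion (1.59 to 2.35), and C57BL/6J infected replicate 5 had -0.06 for cytotoxic effector genes (2.18 to 3.46).

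Among gene levels, BALB/c control replicate 2 stood apart for Aqp6 at 1.67 (others 3.87 to 5.05), Acta1 at 6.67 (8.88 to 10.1), Col22a1 at -3.78 (-1.75 to -1.34), Tnni3k at -0.8 (0.72 to 1.47), Pla2g2f at -0.5 (-3.15 to -2.4) and Fcrls at -2.89 (-1.18 to -0.21). BALB/c control replicate 1 did for Rab6b at -4.4 (-2.92 to -2.15), and C57BL/6J control replicate 5 for Mall at -2.69 (0.2 to 1.27) and Ccl5 at -4.62 (-1.77 to -0.19). BALB/c infected replicate 5 stood apart for Cxcl9 at -3.67 (2.4 to 5.94), Saa3 at -1.36 (3.44 to 5.49) and Ubd at -5.17 (1.08 to 4.73), and BALB/c infected replicate 4 for Camk2n1 at -2.19 (-4.83 to -4.01). C57BL/6J infected replicate 5 did for Serpina3f at -4.9 (-1.92 to -0.94), replicate 2 for Plau at -2.82 (-6.14 to -4.93) and replicate 1 for Fam227b at -6.28 (-5.31 to -4.78).

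Lists with a call in the interaction test at the preset correlation had medians of 1.19 for GTPases, 0.92 for type I interferon genes and 0.91 for MHC class I genes. At the labelled dose of 200 these were 1.48, 1.33 and 1.07, with -1.12 for mast cell and eosinophil markers, 0.65 for oxidative stress defence and 0.64 for ribosomal proteins. None held with an estimated correlation (lowest adjusted p = 0.96 over both doses and 0.88 at 200), and 93 and 79 of 100 divisions of the arrays called as many lists. Oxidative stress defence and ribosomal proteins turned to -0.24 and -0.25 with quantile normalisation and to -0.27 and -0.44 with the deposited value table, and mast cell markers to 0 with normexp. Probes without a gene name, 20499 in number, were outside the gene comparisons. Of them 39 differed between the strains in controls and 40 in infected hearts, and 171 in BALB/c and 87 in C57BL/6J changed at the labelled dose of 200.

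Infected replicate 5 of each strain had control levels of the infection lists. A failed hybridisation was excluded, since a share of at least 0.97 of the 67 strain genes lay nearer the mean of the array's own strain (67 of 67 and 65 of 67). A swap with a control array of the series was excluded, since 0 control arrays reached the lowest GTPase score of the other 10 infected arrays. The lower labelled dose cannot be told apart from other causes within the infected animals, since with 2 such arrays Fisher's exact test gives no p below the 0.455 found. Position stays open too, since both arrays lay in column 3 of slide 2 and column 3 held all arrays of that dose.

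Mitochondrial respiration and fatty acid oxidation, 61 genes together, stood lower in infected hearts. Over the 12 control arrays their score fell with the share of probes well above background (Spearman's rho -0.88, permutation p = 0.00034). Array-wide high signal could thus lower these genes. BALB/c controls had shares of 39.1%, 88.8%, 42.2%, 67.7%, 28.3% and 45.8%, and infected arrays 39.9%, 43.4%, 38.4%, 81.2%, 42% and 67.8%. These similar values argue against a difference in this share as the cause in BALB/c. C57BL/6J controls had 38.9%, 38.9%, 66.1%, 41.4%, 92.8% and 66.2%, and infected arrays 77.2%, 43.2%, 81.9%, 68.1%, 50.2% and 92.1%, so it fits as a cause there. Whether it is the whole cause in C57BL/6J cannot be told. Slide 2 holds none of the 4 arrays of high signal. Its medians at the labelled dose of 200 were -0.84 in BALB/c and -0.31 in C57BL/6J. The infected shares there, 43.4% and 43.2%, lay between those of the controls, 42.2% and 67.7% in BALB/c and 66.1% and 41.4% in C57BL/6J. Medians by slide and strain had an SD of 1.51, so slide 2 does not decide it. An offset between slides was excluded, since each slide held 2 arrays of every group and the medians with slide as a block were -1.01 in BALB/c and -1.13 in C57BL/6J. Within slides the C57BL/6J medians at the labelled dose of 200 ran from -2.89 to 1.42, and position on the slide cannot be told apart from infection.

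Genes that differed between the strains in controls might reflect probes that bind BALB/c sequence less well. This was excluded for the 40 genes higher in BALB/c, whose direction is opposite, and for the 5 lower genes with a further probe, whose 7 further probes all had a difference below -1 (share 1). Array-wide high signal was excluded, since all 67 were called again without the 4 arrays. Position cannot be told apart from strain, since each strain kept its own row. No biological explanation beyond strain was tested.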

How the results depend on the processing

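Fits to single slides, without the 4 arrays of high signal and without infected replicate 5 of each strain were chosen after the data were seen. Counts of genes stayed within 1.5 times of the value reported in 246 combinations of a comparison and an alternative, were higher in 28 and lower in 73. For counts of lists these were 272, 27 and 39. The cause was not tested, except that fits with fewer arrays or genes have fewer to test.

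For infected BALB/c the count was 0 with normexp, all arrays well above background, the mean over probes, slide as a block, no moderation, only the arrays compared, dose 150, without the 4 arrays of high signal and on each slide, 173 with quantile normalisation, 48 with median scaling, 95 with the value table, 676 at dose 200, 541 without the replicates 5, 1220 without these and the 4 arrays, and 0 to 442 with 1 array left out. For C57BL/6J it was 390, 327 and 1825 at dose 200, without the replicates 5 and without these and the 4 arrays, and 0 to 148 with 1 array left out. Between control strains it was 18 with normexp, 36 with the value table, 8 with all arrays well above background, 181 without the 4 arrays, 0 on each slide and 30 to 106. Between infected strains it was 16, 32 and 14 with normexp, quantile normalisation and the value table, 4 with all arrays well above background, 18 with only the arrays compared, 45 and 0 at dose 200 and 150, 220 without the 4 arrays, 43 without the replicates 5, 154 without both, 0 on each slide and 26 to 106. Dose gave 414 and 3085 on slides 2 and 3, where 1 residual degree of freedom was left.

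At dose 200 the BALB/c count was 427 with normexp, 430 with the value table, 224 with all arrays well above background, 1034 without the 4 arrays, 0, 3 and 18 on the slides and 405 to 800. For C57BL/6J it was 97 with all arrays well above background, 141 with only the arrays compared, 1342 without the 4 arrays, 0, 1 and 6 on the slides and 182 to 606. The interaction at this dose gave 3 genes with normexp. Cd160 in C57BL/6J reversed to -0.25 with normexp, from 1.95.

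Lists with an estimated correlation were 17 in infected BALB/c, 16 in each strain at dose 200 and 0 elsewhere. The counts of lists that follow are at the preset correlation. With all arrays well above background they were 17 in C57BL/6J, 18 in C57BL/6J at dose 200, 1 for the interaction, 2 between infected strains and 14 for dose. The interaction gave 1 with normexp, 6 with the value table and at dose 200, 0 at dose 150, 13 without the 4 arrays, 15 without these and the replicates 5, 16 on slide 3 and 0 to 13. Between control strains lists were 2 with normexp, 10 with the value table and 14, 10 and 15 on the slides. Between infected strains they were 0 with normexp, 3 with quantile normalisation, the value table, slide as a block and only the arrays compared, 2 with no filter, 10 and 1 at dose 200 and 150, 14 without both sets, 0 and 28 on slides 1 and 3 and 2 to 17. Dose gave 14 with the value table, 14 without both sets and 17 on slide 3. The interaction at dose 200 gave 11 with median scaling, 17 without the 4 arrays, 14, 11 and 19 on the slides and 3 to 18.

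The correlation of the responses ran from 0.165 to 0.738 over the alternatives. Its jackknife error of 0.637 was computed from the fits that leave out 1 array. Those fits therefore had to lie within it, which says nothing about stability. Replicate numbers follow the order of deposit and were not used to pair arrays, and slide was used as a block instead. A block for the scan date was not run. Low signal over background, with a median of 48% of probes above it, limits the genes that could be measured.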

Other observations

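The splits of lists with an estimated correlation were chosen after the data were seen. The arrays of each comparison were divided anew in 100 ways, or in all 84 at the labelled dose of 200, and a count as large as the real one includes the real division. For the 5 genes of infected BALB/c, 2 of 100 divisions gave as many (highest other 151), a share under 0.05 in a model without slide. Only 100 of the 462 possible divisions were drawn, and a division other than the real one called 151 genes, so chance was not excluded. With slide as a block the differences of the 5 genes were equal to 2 decimals, with standard errors of 0.46 to 1.41 in place of 0.45 to 1.39, and the adjusted p was 0.0591, so the count was 0. Leaving out 1 array gave 0 genes for 16 of 24 arrays. Chance was excluded for the 67 genes between control strains (1 of 100, 6) and the 676 genes of BALB/c at the labelled dose of 200 (1 of 84, 1). That dose was made a comparison of its own after the data were seen, a choice the divisions leave out of account. By these counts chance was not excluded for the 390 genes of C57BL/6J at that dose (5 of 84, highest other 3089) or the 71 genes between infected strains (7 of 100, 10923). Other arrays bear on part of these genes. Of the 370 that rose in C57BL/6J, 338 also rose in BALB/c, against 12.7 if the calls were independent. Of the 71 genes, 22 higher and 19 lower were called likewise in controls, against 0.1 and 0. This argues against chance for the shared genes, though the calls share 1 estimate of spread per gene. For the counts of 0 the divisions decide nothing, since all 100 reach 0. Their highest others were 818 for C57BL/6J, 737 for the interaction, 10872 for dose and 3472 for the interaction at the labelled dose of 200. Divisions with such high counts point to a structure of the samples other than the groups, whose cause was not tested. In the division with the highest count the mean shares of probes well above background in its groups were 45.9% and 75.1% for infected strains, 47.8% and 73.1% for dose, 84% and 49.1% for C57BL/6J at the labelled dose of 200 and 53.9% and 72.3% for C57BL/6J.

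Lists at the preset correlation were called as often in 10 of 100 divisions for infected BALB/c (29 lists, highest other 36), 11 for C57BL/6J (28, 34), 93 for the interaction (3, 34), 58 between control strains (6, 20), 83 between infected strains (5, 30) and 23 for dose (27, 33). At the labelled dose of 200 these were 21 of 84 for BALB/c (24, 31), 8 of 84 for C57BL/6J (28, 33) and 79 of 100 for the interaction (6, 32), so chance was excluded for none. The median of the other divisions was 7 lists between control strains and 16 to 21 in the other comparisons. With an estimated correlation chance was excluded for the 16 lists of each strain at the labelled dose of 200 (1 of 84 each, highest others 13 and 11). Here too the divisions leave out of account that this comparison was chosen after the data were seen. For the 17 lists of BALB/c the share was under 0.05 (2 of 100). A division other than the real one also called 17, and 100 of 462 were drawn, so chance was not excluded there. The other comparisons had 0 such lists, where the divisions decide nothing either, with highest others of 13, 13, 0, 10, 0 and 1.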
